A study of Drosophila melanogaster with 24 samples.

How the data were processed

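Total RNA from dissected female and male genital discs was amplified and hybridised by the authors to Affymetrix Drosophila Genome 2.0 arrays, 1 array per sample. Per the labels, animals were reared at 25 C and carried a GFP marker of imaginal discs, 20 ng of total RNA went into each labelling, and each combination of sex and stage had 4 biological replicates. L3 discs came from wandering larvae. The pupal stages were set by morphology, at peak size of the puparial air bubble (about 6 h APF) for P6 and at the onset of GFP in the eye disc (about 20 h APF) for P20.

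The deposited values are log2 RMA summaries per probe set, made by the authors with RMA, and were used as deposited. The version and settings of RMA are not given, and no background levels or detection calls are given, so signal over background per array is unknown. The table held 18952 probe sets in 24 columns, all of which were assigned to a group. The 183 Affymetrix controls were left out. The platform annotation gave 1 gene to 13647 probe sets, several genes to 402 and none to 4720 (25.1%); the last 2 kinds were left out of the comparisons. Of the probe sets with 1 gene, 13544 matched a Release 6 gene table, used for symbols and chromosomes, and 0 symbols changed. The genome build behind the array annotation is not given in the sources used here, and no coordinates are printed. For the 1094 genes with several probe sets, the one with the highest mean over all arrays was used, which left 11982 genes, of which 11894 had a chromosome and 1873 were X-linked. No filter on low values was applied.

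Differences were tested in R 4.3.3 with limma 3.58.1, in lmFit and eBayes fits of 1 mean per group to all 24 arrays with 18 residual degrees of freedom. Genes passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of a comparison, two-sided, and counts at 2-fold or more are given beside. Log2 differences in the sex comparisons are female minus male, and in the stage comparisons later minus earlier. The sex by stage interaction was a moderated F test with 2 degrees of freedom, followed by its contrasts between successive stages. The median difference over all genes was at most 0.085 log2 units in size in any comparison.

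Gene lists, 28 in number, and X-linked genes were tested with camera in limma, with the correlation between genes preset to 0.01 and, beside it, estimated from the data. Lists with 5 or more measured members were tested, and p was adjusted over the lists of a comparison. Some lists share members, so their calls are not independent. For example, eya is in the patterning and germline lists and verm in the tracheal and apical matrix lists. The lz gene is in the patterning, sensory organ and hemocyte lists. The lists, the comparisons, the tests and the alternatives were chosen before the data were examined, except where the text says otherwise. Overlaps were tested with one-sided Fisher's exact tests.

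Named genes follow a rule fixed with the comparisons. In each comparison of 2 groups, they are the 6 genes with the largest change in each direction among those past the threshold whose 4 values of 1 group all lie beyond the 4 of the other, other than CG and CR numbers, and the largest 2 in each direction among CG and CR numbers. The rule was applied to each sex apart in the stage comparisons, so a gene named for 1 sex may have changed in both. From each list described, up to 4 members with the smallest adjusted p and any member needed to describe it are named. In the sex comparisons a panel was read whatever its values: dsx, tra, Sxl, msl-2, Yp1, lz, dac, bnl, btl, drm, dpp and en, while roX1, roX2, Abd-B, Fas2 and wg, also on the panel, had no probe set assigned to them alone. For the interaction they are the 6 genes with the smallest p, CG and CR numbers aside, and members of the panel and of the lists past the threshold.

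The labels give no batch. Replicate numbers were checked as possible pairs of female and male arrays by the correlation over genes of deviations from the group means. At P20 same-numbered arrays had r of 0.11, 0.42, 0.24 and 0.40, each the highest for its female array, and none of the other stages had this in all 4 arrays. With the number as a block, 291 genes passed at P20, and 415 with a block for each number and stage, against 282 without a block.

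The procedure was tested on simulated data with known changes in 200 of 11982 genes. Changes of 2 log2 units were recovered for 97.0% to 100% of genes in the comparisons of groups, changes of 1 for 67.2% to 80.6% and changes of 0.5 for 19.4% to 25.4%. In the interaction the shares were 93.9%, 49.3% and 2.99%. The simulated noise was independent between arrays, with 1 spread per gene in all groups. Real replicates varied most at L3, and same-numbered arrays correlated, so the shares may not hold there.

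The alternatives tried were median centring of arrays, a mean-variance trend with robust eBayes, leaving out dim genes, the mean of a gene's probe sets, every probe set, the replicate number as a block, the 8 compared arrays alone, leaving out each array in turn, an adjusted p under 0.01, other probe sets of named genes, and for lists the estimated correlation and limma's fry. Chosen after the data were seen were a block for each number and stage, leaving out both L3 replicate 1 arrays, and leaving out genes that follow testis markers, meaning a correlation above 0.7 between a gene's deviations from the group means and the mean of those of 49 listed markers over the male arrays, which 561 genes met with the markers included. Figures were drawn with matplotlib 3.10.9.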

Results

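RNA levels were measured in genital discs of Drosophila melanogaster, the primordium of the internal and external genitalia, in females and males at 3 stages of metamorphosis. L3 discs came from wandering larvae, P6 discs from prepupae at about 6 h after puparium formation (APF), and P20 discs from pupae at about 20 h APF. The 24 arrays form 6 groups of sex and stage with 4 biological replicates each (n = 4 arrays per group throughout). The deposited log2 RMA values (robust multi-array average) ran from 2.04 to 14.06, and array medians lay between 5.06 and 5.21. Correlations between replicates ranged from 0.964 to 0.994. The median SD over genes was 0.247 and 0.250 log2 units in L3 females and males, 0.145 and 0.182 at P6, and 0.193 and 0.191 at P20. The number of arrays limits the precision. The stages separated on components 1 and 2 of the variation between arrays, which held 41.3% and 29.1% of it. Component 3, with 7.02%, parted the sexes at P6 and P20.

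**Figure D1:**
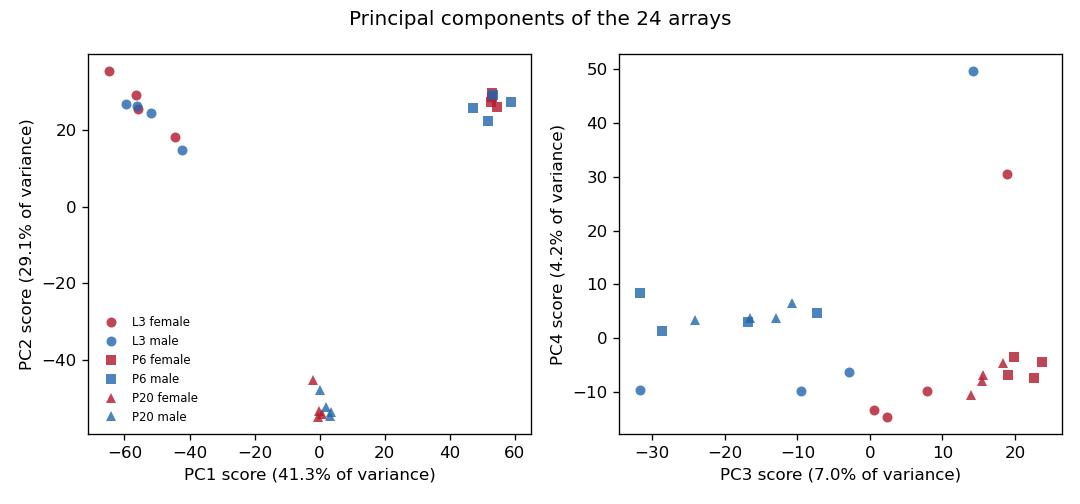
Each point is 1 array placed by its scores on principal components of the log2 RMA values, with the share of variance on each axis. Colour gives the sex and shape the stage. On component 3 the P6 and P20 females lie between 13.9 and 23.7 and the P6 and P20 males between -31.8 and -7.29, while the L3 replicate 1 arrays have the component 4 scores of 30.5 in females and 49.6 in males.

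The comparison of female with male discs at L3 asks which genes already differed between the sexes before metamorphosis. The Runx transcription factor gene lz, needed to form the spermathecae, was higher in female discs, with 9.31 ± 0.12 log2 units (mean ± SD, n = 4) in females and 4.58 ± 0.50 in males (adjusted p = 2.3e-08). Dr, a homeobox gene of the Msx family, was higher in male discs, with 10.75 ± 0.18 in males and 4.89 ± 0.89 in females (adjusted p = 8.11e-09). Higher in males as well were Poxn, a paired-domain gene needed for chemosensory bristles and male genital structures, and bnl, which encodes the fibroblast growth factor (FGF) ligand Branchless. The female minus male log2 difference was -3.33 ± 0.23 (SE) for Poxn and -3.06 ± 0.22 for bnl.

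Among the other genes with the largest female-higher values at L3, the difference was 3.43 for dpr17, which encodes an immunoglobulin-domain protein, 2.70 for the Pax gene eyg and 2.08 for the aquaporin gene Drip. It was 2.05 for the dynein intermediate chain gene Sdic1, 1.86 for the tubulin gene alphaTub85E, 3.18 for CG4267 and 2.51 for CG10184. On the male-higher side it was -2.49 for the forkhead gene slp2, -2.38 for the odorant-binding protein gene Obp99a, -2.24 for the Notch-responsive repressor gene E(spl)m5-HLH, -5.55 for CG13053 and -2.82 for CG4766. Of 11982 genes tested, 118 passed the threshold, 44 of them higher in females and 74 higher in males; 25 and 50 of these differed by 2-fold or more.

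The genital disc patterning list, 27 measured transcription factor and signalling genes, was shifted towards males at L3. Its members bab1 (1.54) and bab2, BTB-domain regulators, and lz were higher in females. The Iroquois gene caup (-1.73), the LIM-homeobox gene ap (-1.40), eya (-1.05), Poxn and 3 others were higher in males, and 17 members did not pass (3 higher and 7 lower over all genes tested, 4 and 11 adjusted over the list alone, camera adjusted p = 1.56e-05). In FGF signalling, 8 genes, bnl and its receptor gene btl (-1.74) were higher in males and htl (0.47), the receptor gene of mesoderm, was higher in females (2 and 4 adjusted over the list alone, adjusted p = 0.00905). The 13 genes of sex determination and dosage compensation held tra (0.92), the female-determining splicing factor gene, above males, and msl-2 (-1.06), of the male dosage compensation complex, and dsx (-0.91), the transcription factor gene at the end of the cascade, below males. Adjusted over the list alone, 1 was higher and 4 were lower (adjusted p = 0.000141). Another probe set of dsx, whose transcripts are spliced differently in the sexes, was higher in females, by 5.48. The list was not tested with that probe set in place of the one used. For Sxl, the switch gene of the cascade, the probe set used gave -0.22 (adjusted p = 0.833) and 2 others gave 1.86 (adjusted p = 0.0112) and -0.29 (adjusted p = 0.905). The bnl difference was -0.25 on another probe set (adjusted p = 0.904) and -3.18 on yet another.

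Among 12 Hedgehog, Wnt and Dpp readouts, bi (-0.63), a T-box gene, and dpp (-0.56), the BMP ligand gene, were lower in females at L3 (0 and 3 adjusted over the list alone, adjusted p = 1.56e-05). Among 11 Notch pathway genes, E(spl)m5-HLH and E(spl)m4-BFM (-0.87) were lower (0 and 3 adjusted over the list alone, adjusted p = 0.00438). No single gene passed over all genes tested in the JNK list of 12 genes (0 higher and 2 lower adjusted over the list alone, adjusted p = 0.00426) or in cell adhesion and junctions, 26 genes (1 and 1 adjusted over the list alone, adjusted p = 0.0443); both lists were shifted towards males. With an estimated correlation the adhesion call was lost (adjusted p = 0.528 with an estimated correlation), while the other lists named for L3 kept theirs. Of 1873 X-linked genes, 11 were higher and 14 lower in females (20 and 17 adjusted over the list alone). Their median difference was 0.06, against 0.01 for the autosome arms (adjusted p = 0.044). Of 20 sensory organ genes, the proneural gene ato (1.31) and lz were higher and sens (-1.25) and Poxn lower, 4 and 5 adjusted over the list alone, and the list itself did not pass (adjusted p = 0.115). The patterning genes dac (-0.34) and en (-0.36), the hindgut gene drm (0.32) and the yolk protein gene Yp1 (0.04) did not pass, with adjusted p between 0.13 and 0.999.

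A fit to the 8 L3 arrays alone passed 44 genes, 13 higher and 31 lower in females. The main fit shares 1 spread per gene over all groups, and replicates varied most at L3, so its adjusted p at L3 may be too small. Fits without 1 array passed 85 to 140 genes, the female-higher genes numbering 24 without male replicate 2. Calls ended for E(spl)m4-BFM without any 1 of the 8 arrays, for htl without any but female replicate 2, for dpp without any but female replicate 2 or male replicate 1, for bi without female replicate 4 or male replicates 1 or 2, and for ato without male replicate 2, with adjusted p up to 0.196, 0.154, 0.176, 0.101 and 0.0596 in turn, and median centring also ended those of E(spl)m4-BFM (adjusted p = 0.0609) and htl (adjusted p = 0.0814).

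The comparison at P6 asks how the sexes differed early in metamorphosis. Dr was higher in males, with 11.04 ± 0.20 log2 units against 4.48 ± 0.99 in females (adjusted p = 5.73e-10). gcm, a transcription factor gene of glia and blood cells, was higher in males, with 8.43 ± 0.14 against 2.94 ± 0.25 (adjusted p = 8.44e-13), and ham, a zinc finger gene, was higher in males too (-4.37). In females lz was higher, with 9.77 ± 0.12 against 4.65 ± 1.21 in males, and so was the uncharacterised gene CG4267 (5.43). The female minus male difference was 3.56 for the peroxidase gene Pxd, 3.46 for eyg, 3.06 and 3.04 for the proneural genes l(1)sc and ato, 2.80 for the homeobox gene unpg and 2.30 for CG11382.

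The male-higher genes at P6 also held transcripts known from the male germline. The difference was -4.22 for Mst77F, which encodes a sperm chromatin protein, -4.15 for Mst84Dc, -4.08 for ocn, -4.58 for CG31226 and -4.48 for CG17376. Of 49 measured testis markers, listed after the data were seen, 18 were lower in females and 0 higher at P6, and 0 passed either way at L3. In total 579 genes passed, 133 higher in females and 446 higher in males, of which 73 and 254 differed by 2-fold or more. Without the markers and the genes that followed them over the male arrays, a count chosen after seeing the data, 388 genes passed, 131 higher in females and 257 higher in males. Without the P6 male replicate 3 array the count was also 388, with 276 higher in males.

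Genital disc patterning was shifted towards males at P6, with 4 members higher and 11 lower in females (4 and 13 adjusted over the list alone, adjusted p = 0.000158). The difference was -3.21 for Poxn, -2.22 for eya, -2.23 for ap and -1.71 for dac. This call was lost with the other setting of the test (adjusted p = 0.166 with an estimated correlation). The germline and gonad list, 21 genes, held eya, ocn, the testis tubulin gene betaTub85D (-2.54) and Mst98Cb (-1.55) below males and none above (0 and 6 adjusted over the list alone, adjusted p = 0.00313). That call was lost too (adjusted p = 0.166 with an estimated correlation). The innate immunity list, 11 genes, was shifted upwards in females with no member past the threshold (0 and 0 adjusted over the list alone, median 0.89, adjusted p = 0.00313). It had adjusted p = 0.307 with an estimated correlation, and 0.25 without P6 female replicate 2.

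Several lists that did not pass as a whole at P6 held single genes that differed. Sex determination and dosage compensation had tra (0.66) higher and msl-2 (-1.07), dsx (-0.85) and the acetyltransferase gene mof (-0.65) lower (1 and 3 adjusted over the list alone, adjusted p = 0.127). The other probe sets gave 4.67 for dsx and 1.46 and -0.01 for Sxl, whose used probe set gave -0.22 (adjusted p = 0.517). FGF signalling had htl (0.75) higher and bnl (-2.60) and btl (-1.17) lower (1 and 3 adjusted over the list alone, adjusted p = 0.0832), while other probe sets of bnl gave -2.07 (adjusted p = 1.89e-07) and -0.32 (adjusted p = 0.526). Among 20 sensory organ and bristle precursor genes, l(1)sc, ato and lz were higher and Poxn lower (5 and 3 adjusted over the list alone, adjusted p = 0.132); the list's median was -0.03, its mean 0.36 and its test upwards. Among 17 tracheal markers the nuclear receptor gene kni (1.72), its relative knrl and the POU gene vvl (1.10) were higher and sano (-1.04) and btl lower (4 and 2 adjusted over the list alone, adjusted p = 0.0803). Among 18 hemocyte markers lz was higher, and gcm, its paralog gcm2 (-1.45) and the peroxidasin gene Pxn (-0.88) were lower (1 and 3 adjusted over the list alone, adjusted p = 0.879); the median was 0.12, the mean -0.03 and the test downwards. In the JNK list, scaf (1.39), a protease homologue, was higher and the TNF ligand gene egr (-0.63) lower (1 and 1 adjusted over the list alone, adjusted p = 0.127). Of 36 cuticle protein genes, the pupal cuticle gene Pcp (-3.88) and Cpr64Aa (-1.22) were lower (0 and 2 adjusted over the list alone, adjusted p = 0.961), with a median of 0.01, a mean of -0.11 and a test downwards.

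X-linked genes had a median difference of 0.05 at P6, against -0.02 for the autosome arms, with 32 higher and 51 lower (32 and 50 adjusted over the list alone, adjusted p = 0.0593 and adjusted p = 0.0132 with an estimated correlation). Among the panel of genes read at every stage, en (-0.57) was lower in females, while dpp (-0.46, adjusted p = 0.0502), drm (0.25) and Yp1 (-0.07) did not pass.

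Single arrays decided some calls at P6: CG11382 did not pass without female replicates 1 or 2 or male replicate 4, Cpr64Aa without female replicates 1, 2 or 3 or male replicate 2, Mst98Cb without female replicate 4 or male replicates 2 or 3, Pxn without any female or male replicate 3, betaTub85D without male replicate 3, and egr without any array but male replicate 2, with adjusted p up to 0.06, 0.0798, 0.0983, 0.0889, 0.0623 and 0.157 in turn. Other probe sets of egr, sano and vvl differed the same way and did not pass (adjusted p = 0.327, 0.0527 and 0.267), and another of Pxn gave 0.10 (adjusted p = 0.999).

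The comparison at P20 asks how the sexes differed once the pupal genital structures were forming. lz was higher in females, with 10.68 ± 0.31 log2 units against 3.52 ± 0.10 in males (adjusted p = 1.11e-11), and eg, a nuclear receptor gene, was higher in females too (4.86). Poxn was higher in males, with 9.09 ± 0.16 against 4.84 ± 0.45 (adjusted p = 2.94e-11). prt, which encodes a vesicular transporter, was higher in males, with 6.44 ± 0.37 against 2.84 ± 0.20 (adjusted p = 3.81e-13). The difference was 4.15 for dpr17, 3.86 for the BTB-domain gene lov, 3.81 for eyg, 3.28 for the cuticle protein gene Cpr62Bc, 3.98 for CG4267 and 3.34 for CG11570. It was -3.98 for Dr, -4.65 for Mst84Dc, -3.92 for ocn, -3.89 for Mst77F, -4.28 for CG31226 and -3.98 for CG17376.

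In total 282 genes passed at P20, 84 higher in females and 198 higher in males, of which 58 and 142 differed by 2-fold or more. Of the 49 testis markers, 4 were lower in females and 0 higher. Without the markers and the genes that followed them, 242 genes passed, 83 higher and 159 lower.

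The sensory organ and bristle precursor list was shifted towards males at P20. Of its 20 genes, lz was higher in females, and Poxn, the proneural genes sc (-1.33), ac (-1.49) and ase (-1.32), sens (-1.28) and the nuclear receptor gene svp (-1.49) were lower (1 and 7 adjusted over the list alone, adjusted p = 4.18e-07). The Notch pathway list was shifted the same way, with E(spl)m4-BFM (-1.62) and E(spl)m5-HLH (-1.85) lower (0 and 3 adjusted over the list alone, adjusted p = 0.000715). Genital disc patterning had bab1 (2.14) and 2 other members higher and eya (-1.85), en (-0.62) and 5 others lower (4 and 12 adjusted over the list alone, adjusted p = 0.000694, but adjusted p = 0.208 with an estimated correlation). The germline and gonad list had eya and ocn lower (0 and 3 adjusted over the list alone, adjusted p = 0.0128, but adjusted p = 0.208 with an estimated correlation). Hemocyte markers were shifted upwards in females with lz as the member past the threshold (2 and 0 adjusted over the list alone, adjusted p = 0.0127, but adjusted p = 0.441 with an estimated correlation). Salivary gland markers, 13 genes, were shifted upwards with no member past the threshold (0 and 0 adjusted over the list alone, adjusted p = 0.00833, but adjusted p = 0.208 with an estimated correlation). X-linked genes had a median of 0.05, against -0.01 for the autosome arms, with 22 higher and 29 lower (24 and 32 adjusted over the list alone, adjusted p = 0.0127). The sensory, Notch and X-linked calls held with an estimated correlation.

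Of 36 cuticle protein genes, Cpr62Bc, Cpr66Cb (2.49) and TwdlT (2.53) were higher in females at P20 and 6 were lower, among them Cpr66D (-3.46), Cpr64Aa (-2.57) and Cpr92F (-2.11); 4 were higher and 7 lower adjusted over the list alone, and the list did not pass (adjusted p = 0.0879). Of 18 apical matrix and chitin genes, the zona pellucida domain genes dy (2.95) and tyn (1.67) and the actin-bundling gene f (1.02) were higher and none lower (3 and 0 adjusted over the list alone, adjusted p = 0.0979). The myogenic factor gene nau (2.86) was higher in females, and prd (-2.998), a Pax gene needed for male accessory glands, was lower. In sex determination and dosage compensation, tra (0.80) and fru (1.24) were higher and msl-2 (-0.98), dsx (-0.84) and mof (-0.67) lower (2 and 4 adjusted over the list alone, adjusted p = 0.0879). The other probe sets gave 4.82 for dsx and 1.67 and -0.07 for Sxl, whose used probe set gave -0.08. bnl (-0.67, adjusted p = 0.179), btl (0.34), dac (0.48), dpp (-0.15), drm (0.10) and Yp1 (-0.01) did not pass.

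Single arrays decided some calls at P20: CG11570 did not pass without female replicate 4 or any male, ocn without male replicate 3, fru without female replicate 2, svp without any array but female replicate 2 or male replicates 1 or 4, and tyn without female replicates 1 or 4 or male replicates 1 or 3, with adjusted p up to 0.102, 0.0696, 0.0588, 0.111 and 0.0851 in turn. Of 2 other probe sets each, CG17376 had -3.34 (adjusted p = 0.00365) and -1.72 (0.146), svp -1.12 (0.0261) and -0.40 (0.6), and bnl -1.03 (0.00224) and 0.02 (0.999), while those of f (0.864) and fru (0.441 to 0.981) differed the same way and did not pass.

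**Figure D2:**
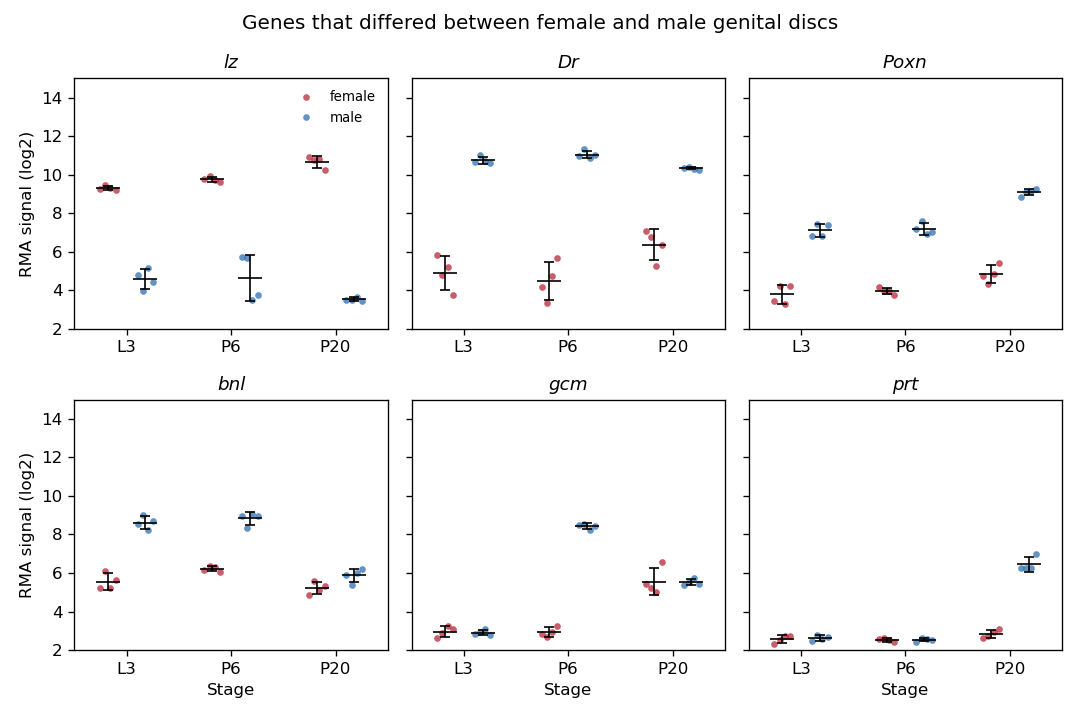
Log2 RMA values of 6 genes in each array (points), with the mean and SD of each group (n = 4), by stage on the horizontal axis and coloured by sex. The gcm means at P6 are 2.94 in females and 8.43 in males, against 2.95 and 2.91 at L3 and 5.55 and 5.53 at P20.

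Sex differences overlapped between stages. Of the 762 genes that passed at 1 stage or more, 34 passed at all 3, 10 higher and 23 lower in females each time. The 23 hold dsx by the probe set used, while another of its probe sets was higher in females each time. Among the 34, chosen after their values were seen, were al and bab2 on the female side and salm and salr on the male side. These 4 genes encode transcription factors. The remaining gene of the 34, Jhbp2, also chosen after its values were seen, was lower in females at L3 (-1.15) and higher at P6 (0.87) and P20 (2.30). Its L3 call ended without female replicates 1 or 4 or male replicates 1 or 4 (adjusted p up to 0.0752) and its P6 call without any array but male replicate 4 (adjusted p up to 0.133). L3 and P6 shared 21 female-higher and 38 male-higher genes, against 0.488 and 2.75 expected for independent sets (one-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 3.12e-30 and 6.45e-35). P6 and P20 shared 33 and 100, against 0.932 and 7.37 expected (adjusted p = 9.89e-44 and 2.74e-91). The male-higher genes held 18 testis markers and 171 genes that followed them of 446 at P6, and 4 and 35 of 198 at P20. The overlap was not counted without them. The spread estimate of each gene is shared by all stages, so the sets are not fully independent. L3 and P20 shared 17 and 36, against 0.308 and 1.22 expected (adjusted p = 2.53e-26 and 4.32e-45). Of the genes that passed at both stages of a pair, 59 of 60, 133 of 136 and 53 of 55 had the same direction.

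The sex by stage interaction asks for which genes the sex difference itself changed over the stages, and 198 genes passed. The gcm difference was 0.04 at L3, -5.49 at P6 and 0.02 at P20 (adjusted p = 9.12e-11 for the F test over the stages). That of prt was -0.04, -0.02 and -3.60 (adjusted p = 9.12e-11), and that of prd was 0.11, -1.76 and -2.998 (adjusted p = 2.29e-07). For l(1)sc, scaf and unpg the difference was largest at P6, at 3.06, 1.39 and 2.80, while at L3 and P20 it lay between -0.30 and 0.64 (adjusted p = 4.63e-07 for each). The male excess of bnl ran from -3.06 at L3 through -2.60 to -0.67 at P20 (adjusted p = 0.000101), and that of btl from -1.74 through -1.17 to 0.34 (adjusted p = 6.06e-05). The dac difference was -0.34, -1.71 and 0.48 (adjusted p = 3.35e-05), and the lz difference was 4.72, 5.12 and 7.15 (adjusted p = 0.0191).

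Between L3 and P6 the sex difference rose for 39 genes and fell for 58, and the sensory organ, Notch and JNK lists moved towards females. In the sensory list l(1)sc (2.42) and ato (1.72) rose (2 and 0 adjusted over the list alone, adjusted p = 0.000284). In the JNK list scaf (1.60) rose (2 and 0 adjusted over the list alone, adjusted p = 0.000284), and in the Notch list no member passed over all genes tested (2 and 0 adjusted over the list alone, adjusted p = 0.000284). Between P6 and P20 it rose for 59 genes and fell for 79, and the same lists moved towards males; this contrast and that from L3 to P6 share the P6 arrays with opposite sign, so their moves are not independent. In the sensory list l(1)sc (-3.22), ato (-2.77), ac (-2.17), svp (-2.15) and sc (-1.90) fell (1 and 9 adjusted over the list alone, adjusted p = 4.5e-10). In the Notch list E(spl)m4-BFM (-1.40) fell (1 and 6 adjusted over the list alone, adjusted p = 2.11e-06), and in the JNK list scaf (-1.68) and the metalloprotease inhibitor gene Timp (-1.65) fell (0 and 2 adjusted over the list alone, adjusted p = 0.00963). These 6 calls held with an estimated correlation.

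Other lists moved between stages in their sex difference by the preset test, but not with an estimated correlation. From L3 to P6 the germline and gonad list moved towards males, with eya (-1.17) and mia (-0.81) falling (0 and 2 adjusted over the list alone, adjusted p = 0.00448, but adjusted p = 0.156 with an estimated correlation). The cell cycle list moved the same way with no member past the threshold (0 and 0 adjusted over the list alone, adjusted p = 0.0014, but adjusted p = 0.216 with an estimated correlation). Innate immunity and salivary gland markers moved towards females, with no member past the threshold in either (0 and 0 adjusted over the list alone in each, adjusted p = 0.00125 and 0.0267, but adjusted p = 0.291 and 0.314 with an estimated correlation). The innate immunity call was also lost without P6 female replicate 2, a refit chosen after seeing the data (adjusted p = 0.227). From P6 to P20 hemocyte markers moved towards females, with gcm (5.51) and gcm2 (1.58) rising (4 and 0 adjusted over the list alone, adjusted p = 0.00231, but adjusted p = 0.45 with an estimated correlation).

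The step from L3 to P6 asks what changed as the larval disc became prepupal, and it was measured in each sex. Osi6, of the Osiris family of apical membrane proteins, was higher at P6 in females, with 12.96 ± 0.07 log2 units against 3.58 ± 0.48 (adjusted p = 1.39e-16), and in males, with 12.86 ± 0.06 against 3.16 ± 0.15 (adjusted p = 7.46e-17). The cuticle protein gene Lcp65Ad rose by 8.59 in females and 8.83 in males. Kr-h1, the transcription factor gene of the juvenile hormone response, fell by 6.47 in females and 5.76 in males, from 10.26 ± 0.24 to 3.79 ± 0.11 and from 10.35 ± 0.26 to 4.60 ± 1.05. The crystal cell prophenoloxidase genes PPO1 and PPO2 fell by 5.87 and 5.96 in females and by 5.74 and 6.09 in males.

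In females the zona pellucida domain genes dyl and dy rose by 8.27 and 7.88 from L3 to P6, Jhbp4 by 8.12, the Tweedle cuticle gene TwdlT by 7.64, CG9083 by 8.98 and CG4998 by 8.95. In males Osi14 rose by 8.23, TwdlT by 7.49, Osi2 by 7.33, Jhbp4 by 7.23, CG4998 by 8.88 and CG14107 by 8.59. The odorant-binding protein gene Obp56a fell by 6.97 in females and 6.16 in males, and the muscle Z-disc gene Zasp66 by 6.25 and 6.23. Jhbp7 fell by 6.64 in females. The crystallin-related gene l(2)efl fell by 5.68 in males and 5.44 in females. Its other probe sets gave -5.02 (adjusted p = 3.42e-11) and -0.24 (adjusted p = 0.428) in males. In females they gave -5.22 (adjusted p = 1.57e-11) and -0.30 (adjusted p = 0.295). CG11854 fell by 7.67 in females and 6.83 in males, CG40486 by 7.06 in females and 5.95 in males, and CG15353 by 6.72 in males.

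Tracheal markers, whose list holds Osiris genes, rose from L3 to P6, with Osi9 (6.32 in females, 5.98 in males) and Osi7 (6.95 and 6.96) among 11 higher and 1 lower of 17 in females (12 and 2 adjusted over the list alone, adjusted p = 1.28e-08). In males 11 were higher and 3 lower (13 and 3 adjusted over the list alone, adjusted p = 2.45e-07). Apical matrix and chitin genes rose, with the chitin deacetylase gene verm (3.82 and 3.81) and dy (7.88 and 6.98) among 11 higher and 2 lower of 18 in females (11 and 2 adjusted over the list alone, adjusted p = 3.98e-05). In males 11 were higher and 3 lower (12 and 3 adjusted over the list alone, adjusted p = 0.000192). Both lists held with an estimated correlation in both sexes. Of 36 cuticle protein genes, 15 rose and 4 fell in females (15 and 4 adjusted over the list alone, adjusted p = 0.00246, but adjusted p = 0.0817 with an estimated correlation). In males 14 rose and 6 fell (15 and 7 adjusted over the list alone, adjusted p = 0.00187, but adjusted p = 0.0936 with an estimated correlation). Of 26 ecdysone response genes, 14 rose and 3 fell in females, among them ImpL1 (6.66) and Edg78E (6.21), both induced by the hormone, and the protease gene Sb (3.72) (14 and 3 adjusted over the list alone, adjusted p = 0.000108, held with an estimated correlation). In males 10 rose, ImpL1 by 5.92 and Edg78E by 5.55, and 4 fell (10 and 4 adjusted over the list alone, adjusted p = 0.00515, but adjusted p = 0.0936 with an estimated correlation).

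The cell cycle list of 28 genes fell from L3 to P6. The centralspindlin gene tum (-1.59 in females, -1.09 in males), the kinase gene aurB (-1.51 and -1.05) and Incenp (-1.44 and -1.18), genes of cell division, were among 18 lower and 0 higher in females (0 and 19 adjusted over the list alone, adjusted p = 4.17e-06, held with an estimated correlation). In males 13 were lower and 1 higher (1 and 13 adjusted over the list alone, adjusted p = 0.000437, but adjusted p = 0.133 with an estimated correlation). Sensory organ and bristle precursor genes rose, with l(1)sc (2.51), sens (2.07), sc (1.63) and cato (1.53) among 11 higher of 20 in females (11 and 0 adjusted over the list alone, adjusted p = 1.91e-05, held with an estimated correlation). In males sens (1.20), sc (1.06) and cato (1.35) were among 8 higher (8 and 0 adjusted over the list alone, adjusted p = 0.0119, but adjusted p = 0.0936 with an estimated correlation). In females the Notch list rose, with E(spl)m7-HLH (2.01) among 7 higher and 2 lower of 11 (7 and 2 adjusted over the list alone, adjusted p = 0.00311), and so did the JNK list, with scaf (1.39) among 8 higher and 2 lower of 12 (8 and 3 adjusted over the list alone, adjusted p = 0.00742), and both held with an estimated correlation. In males these lists did not pass (adjusted p = 0.355 and 0.649), with 5 and 1 and with 4 and 3 members higher and lower (5 and 1 and then 5 and 3 adjusted over the list alone). Hemocyte markers fell, with eater (-4.38 and -4.78), a phagocytosis receptor gene, and Nplp2 (-4.61 and -4.58) among 9 lower and 2 higher of 18 in females (2 and 9 adjusted over the list alone, adjusted p = 0.00181, but adjusted p = 0.384 with an estimated correlation). In males 11 were lower and 3 higher, among these gcm (5.52) (3 and 12 adjusted over the list alone, adjusted p = 0.00685, but adjusted p = 0.521 with an estimated correlation).

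In total 4264 genes passed from L3 to P6 in females, 1752 higher and 2512 lower at P6, of which 851 and 813 changed by 2-fold or more. In males 4165 passed, 1952 higher and 2213 lower, of which 893 and 662 changed by 2-fold or more. Both sexes shared 3148 of these genes, and 3135 of them had the same direction.

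**Figure D3:**
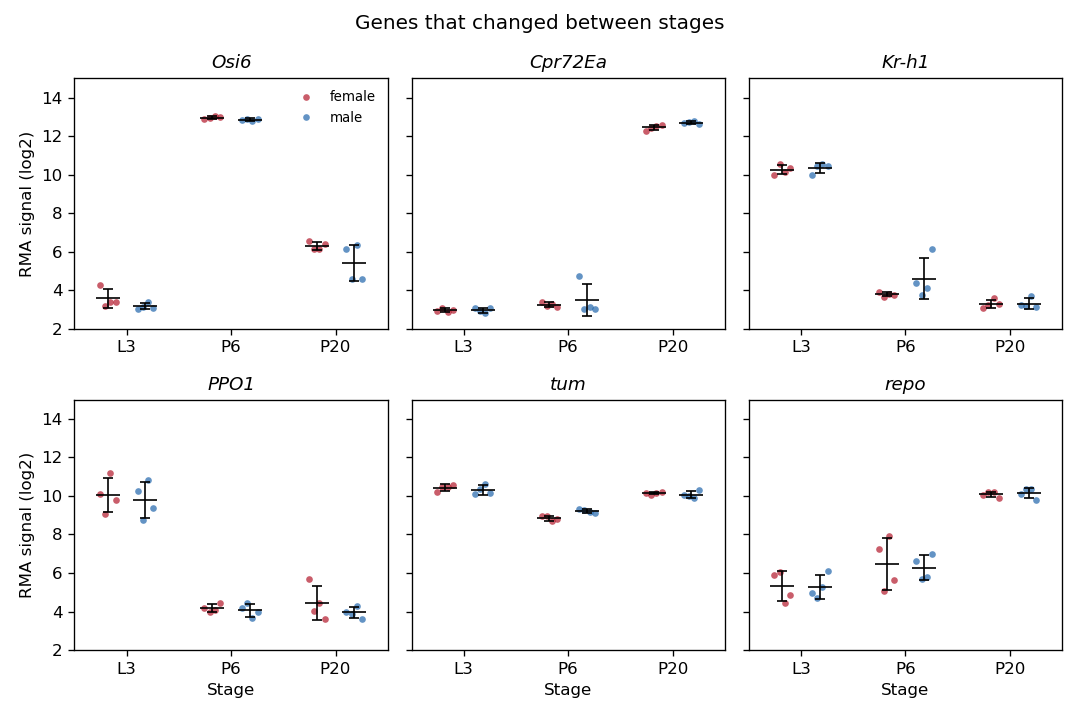
Log2 RMA values of 6 genes in each array (points), with the mean and SD of each group (n = 4), by stage on the horizontal axis and coloured by sex. Osi6 has group means of 3.58 and 3.16 at L3 in females and males, 12.96 and 12.86 at P6, and 6.30 and 5.42 at P20.

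The step from P6 to P20 asks what changed as the pupal genitalia took shape, again in each sex. The cuticle protein gene Cpr72Ea was higher at P20 in females, with 12.45 ± 0.12 log2 units against 3.25 ± 0.12 (adjusted p = 7.09e-18), and in males, with 12.70 ± 0.07 against 3.49 ± 0.83 (adjusted p = 5.24e-18). Jhbp7 and Obp56a, which had fallen by P6 in females, rose by 8.65 and 7.94 in females, and they rose by 8.18 and 7.41 in males. Eip93F, an ecdysone-induced transcription factor gene, rose by 5.27 in females and 4.47 in males. Osi6 fell by 6.67 and 7.44, Osi7 by 6.76 and 6.70, and Osi14 by 6.89 and 6.99.

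The noncoding RNA gene pncr004:X rose by 7.25 in females and 5.79 in males from P6 to P20, and CG34247 by 8.86 and 8.12. In females Qsox2, which encodes a sulfhydryl oxidase, rose by 5.53 and CG13053 by 8.68. In males Ktch rose by 5.46 and lmd, a transcription factor gene of myoblast fusion, by 5.27. CG13023 rose by 7.75 in males and 7.98 in females. Jhbp4 fell by 8.04 in females and 7.44 in males, the sulfotransferase gene St4 by 6.79 and 6.78, CG9083 by 9.03 and 8.36, and CG34115 by 7.80 and 7.75. TwdlT fell by 8.13 in males and dyl by 6.79 in females.

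The cell cycle list rose from P6 to P20, with tum (1.30 in females, 0.84 in males), CycE (1.13 and 1.26), CycB (1.17 and 0.99) and aurB (1.14 and 0.88), genes of cell division and its entry. In females 22 of 28 were higher and 0 lower (25 and 0 adjusted over the list alone, adjusted p = 4.24e-10), and in males 20 were higher and 0 lower (21 and 0 adjusted over the list alone, adjusted p = 1.39e-08). Tracheal markers fell, with Osi9 (-6.22 and -6.03), the chitin deacetylase gene serp (-4.30 and -3.81) and verm (-4.87 and -4.60), with 6 higher and 9 lower of 17 in females (6 and 9 adjusted over the list alone, adjusted p = 0.000521). In males 5 were higher and 9 lower (6 and 11 adjusted over the list alone, adjusted p = 0.000267). These calls on both lists held with an estimated correlation. Cell adhesion and junction genes rose, with the septate junction gene Lac (0.74 and 0.57) and the polarity gene crb (1.17 and 0.96), 15 higher and 1 lower of 26 in females (15 and 1 adjusted over the list alone, adjusted p = 0.000521, but adjusted p = 0.305 with an estimated correlation). In males 14 were higher and 0 lower (16 and 1 adjusted over the list alone, adjusted p = 0.000122, but adjusted p = 0.269 with an estimated correlation).

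Other lists that passed from P6 to P20 did so in 1 sex or lost their call with an estimated correlation. In females genital disc patterning rose, with dac (2.35), ap (1.98) and bab1 (1.67) among 12 higher and 3 lower (13 and 3 adjusted over the list alone, adjusted p = 0.0187, but adjusted p = 0.407 with an estimated correlation). Sex determination and dosage compensation rose, with msl-1 (1.09), msl-2 (0.66) and tra (0.50) among 5 higher and 0 lower in females (5 and 0 adjusted over the list alone, adjusted p = 0.0472, but adjusted p = 0.305 with an estimated correlation). In males her (0.96) and msl-2 (0.56) were among 5 higher and 1 was lower (6 and 1 adjusted over the list alone, adjusted p = 0.0422, but adjusted p = 0.348 with an estimated correlation). In males the sensory list rose, with the ubiquitin ligase gene neur (1.59), svp (2.30) and ase (1.14) among 7 higher and 1 lower (8 and 1 adjusted over the list alone, adjusted p = 0.021, but adjusted p = 0.168 with an estimated correlation). Hemocyte markers fell in males, with the collagen genes vkg (-3.67) and Col4a1 (-3.12) and He (-3.41) among 7 lower and 2 higher (2 and 7 adjusted over the list alone, adjusted p = 0.019, but adjusted p = 0.481 with an estimated correlation). Muscle and myoblast markers rose in males, with the nephrin-family genes sns (2.77) and hbs (1.41) among 6 higher and 1 lower of 18 (8 and 1 adjusted over the list alone, adjusted p = 0.0269, but adjusted p = 0.427 with an estimated correlation). Neuron markers rose in males, with futsch (2.73) and elav (1.38) among 5 higher and 0 lower of 16 (5 and 0 adjusted over the list alone, adjusted p = 0.0413, but adjusted p = 0.427 with an estimated correlation). The futsch gene rose in females as well, by 2.29. Glia markers rose in females, with the glial homeobox gene repo (3.62), wrapper (2.89) and moody (0.95) among 4 higher and 1 lower of 10 (4 and 1 adjusted over the list alone, adjusted p = 0.0341, but adjusted p = 0.123 with an estimated correlation). The repo gene rose in males as well, from 6.27 to 10.16. A list that passed in 1 sex is not thereby shown to differ between the sexes. The muscle, neuron and glia lists did not pass in the change of the sex difference from P6 to P20.

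In total 3154 genes passed from P6 to P20 in females, 1705 higher and 1449 lower at P20, of which 517 and 626 changed by 2-fold or more. With median centring the larger side turned in females, with 1467 higher and 1534 lower. In males 3074 passed, 1570 higher and 1504 lower, of which 492 and 593 changed by 2-fold or more. The larger side turned in males too, with 1341 higher and 1371 lower without P6 male replicate 2, 1260 and 1274 without replicate 3, and 1465 and 1479 without replicate 4. Both sexes shared 2310 of these genes, and 2297 of them had the same direction. Other probe sets of ap in females (0.53, adjusted p = 0.0838) and of futsch in both sexes did not pass. Those of futsch gave 0.07 and 0.00 in males (adjusted p = 0.72 and 0.998) and 0.13 and 0.13 in females (adjusted p = 0.475 and 0.555). Of 2 others of svp in males 1 passed (1.29, adjusted p = 0.00111) and 1 did not (0.48, adjusted p = 0.106).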

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

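The splits of the arrays, the tests of the directions of L3 genes, and the weighing of testis transcripts, of the female replicate 4 arrays and of the L3 replicate numbers were all chosen after the results were seen.

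At P6 more genes were higher in males (446) than in females (133), and 18 of 49 testis markers were lower in females. Scaling of the arrays is argued against as the whole cause, since 381 of the 535 genes that passed after median centring (71.2%) were higher in males. Whether RNA of testis is the whole cause stays open. Without the markers and the genes that followed them, male-higher genes still outnumbered female-higher ones 1.96-fold. Testis transcripts present in similar amounts in all male arrays would not follow the markers, so they could remain in that count. For the testis transcripts themselves, 171 of the other 428 male-higher genes (39.95%) followed the markers over the male arrays, against 4.29% of all genes, which is consistent with RNA of testis carried over in an amount that differed between arrays. Expression in the male disc itself stays open and was not tested, and the marker list was written from the pattern.

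Of the 49 testis markers, 26 were highest among the females in replicate 4 at L3 and 25 at P6, with median shifts of 0.26 and 0.11 from the other females, against 8 at P20. ocn was at 5.19 there at L3, above the male mean of 4.21, and at 5.06 at P6, against means of 2.95 and 2.84 in the other females, CG31226 was at 7.03 at L3 and CG17376 at 5.40 at P6. A large share of male discs among the female ones is argued against. Strongly male-higher genes that do not follow the markers shifted in these arrays by a median of at most 0.21 log2 units. Males exceeded females in these genes by 2.59. The genes were picked in a fit that includes the replicate 4 arrays, which favours genes with small shifts there. A small share of male discs is therefore not excluded. Beyond these shifts, carry-over of testis RNA into these arrays was not tested, and no biological explanation was tested.

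At L3 arrays with the same replicate number deviated together in females and males, with a mean r over genes of 0.357. That was the highest of the 24 pairings of female with male arrays, with 0.354 next, and the same held at P6 (0.157) and P20 (0.293); the exact one-sided permutation p was 0.0417 at each stage, the smallest the pairings can give. This may reflect a preparation shared by arrays of 1 number. RNA of other larval tissues in replicate 1 cannot be told apart from this: 4 of 7 tissue marker lists, those of fat body, hemocytes, muscle and gut, lay above the group means in both replicate 1 arrays, and those of salivary gland, neurons and glia did not. No biological explanation was tested, since the design gives none.

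At L3 the count of genes by itself does not exclude chance: of the 35 splits of the 8 arrays into groups of 4, 5 passed at least as many genes as the real 118. The highest other, 1126 genes, set replicates 1 and 2 of both sexes against replicates 3 and 4, which points to a structure of the samples by replicate number. All other splits at or above 118 kept both replicate 1 arrays together, and both replicate 2 arrays together. Of the 8 splits of the L3 arrays that part all same-numbered pairs, the highest other gave 15 genes, but 8 are too few for a share under 0.05. Of the L3 genes that also passed at P6 or P20, 59 of 60 and 53 of 55 had the same direction on those other arrays, which argues against chance for these genes. Chance in the L3 arrays was also tested by the share of L3 genes that keep their direction at P6 and P20, 85.6% and 87.3% of all 118, and 64.9% and 75.7% of the 37 that passed at neither. This test decides nothing, for all 118 or for the 37: the other splits of the P6 and P20 arrays that came highest, with 85.6% and 86.4%, and 67.6% and 81.1%, kept 3 of 4 females together and so carry the sex difference themselves. Without the replicate 1 arrays the 10 possible splits are too few for a share under 0.05, with 131 genes for the real split, 143 for the highest other and 2 splits at or above the real one. At P6 1 of 35 splits, the real one with 579 genes, was as large and the highest other gave 41. That other split set replicates 1 and 2 of both sexes against replicates 3 and 4. With the pairing left aside, chance is excluded at P6. Same-numbered arrays deviated together at P6 as well, and only 8 splits part all such pairs. With the pairing kept, the splits thus do not settle chance at P6. At P20 1 of 35 splits, the real one with 282 genes, was as large and the highest other gave 2. Only 8 of these splits part all same-numbered pairs, and the highest other of them gave 0. They are too few for a share under 0.05, so with the pairing kept the splits do not settle chance at P20. Chance is excluded from L3 to P6 in females (1 of 35, real 4264, highest other 888) and males (1 of 35, real 4165, highest other 1613). From P6 to P20 chance is excluded in females (1 of 35, real 3154, highest other 1) and males (1 of 35, real 3074, highest other 80). For the interaction 2 of 100 drawn splits, the real one included, lay at or above the real 198. The highest other gave 351 genes and turns the sexes over at P6. The drawn splits also break up the sex difference that the stages share, so they do not stand for an unchanged sex difference. They do not settle chance for the interaction.

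Single arrays lay far from the others of their group in 18 of 258 groups of values of named genes, where chance flags about 1 in 20 groups, here 12.9. CG4267 was at 9.19 in P20 female replicate 4, and unpg at 3.78 in P20 female replicate 3. Obp99a was at 10.39 in L3 male replicate 2 and at 11.80 in P20 male replicate 1. CG4766 was at 8.95 and dac at 10.71 in P20 female replicate 1. CG11382 was at 8.10 and msl-2 at 9.53 in L3 male replicate 1. lov was at 4.62 in P20 male replicate 3 and en at 9.83 in P6 male replicate 2. prt was at 6.99, Sxl at 11.76 and msl-2 at 9.46 in P20 male replicate 4, and msl-2 was at 8.50 in P20 female replicate 4. The values of ocn, CG31226 and CG17376 given above complete the 18.

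Of 174 groups of list means, 10 had such an array, where chance gives about 8.70. The cell cycle mean was 9.83 and the tracheal mean 6.85 in L3 male replicate 4. The cell adhesion mean was 10.15 in P20 female replicate 4, and the ribosomal protein mean was 12.18 in P6 female replicate 3. The mean of accessory structure genes was 4.71 in L3 female replicate 4, 5.01 in L3 male replicate 2 and 4.75 in P20 male replicate 3. The X-linked mean was 7.06 in L3 female replicate 1, 7.002 in L3 male replicate 1 and 6.99 in P6 male replicate 2.

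The sex difference changed between stages, by the test of the interaction, for prt and gcm (adjusted p = 9.12e-11 each), prd (2.29e-07), l(1)sc, scaf and unpg (4.63e-07 each), bnl (0.000101), btl (6.06e-05), dac (3.35e-05) and lz (0.0191). With an estimated correlation it changed from L3 to P6 for the Notch list (adjusted p = 0.00653), the JNK list (0.00653) and the sensory list (0.0116), and from P6 to P20 for the Notch list (0.000867), the JNK list (0.0317) and the sensory list (0.000282).

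Among probe sets without a single gene, which no comparison uses, 28 passed between the sexes at L3, 66 at P6 and 49 at P20.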

How the results depend on the processing

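The block within stage, the interaction of innate immunity without P6 female replicate 2, leaving out both L3 replicate 1 arrays and leaving out testis-following genes were chosen after seeing the data. Of 71 alternatives for counts set beforehand, single arrays left out apart, 64 stayed within 1.5 times the value reported; for those that did not, the cause was not tested. At L3 the 8 arrays alone gave 44 genes against 118, at P6 435 against 579 and at P20 397 against 282. The main fit shares 1 spread per gene over all groups. The median SD was 0.247 and 0.250 in L3 females and males, against 0.145 to 0.193 in the other groups. Adjusted p at L3 may thus be too small. The replicate block gave 131 genes at L3, and a block within stage gave 242, where 3 of 4 females correlated best with the male of their own number, 789 at P6, where 2 of 4 did, and 304 in the interaction. List calls, 59, became 30 with the estimated correlation (29 kept), 93 in fry by direction (52 kept) and 167 in fry without direction (51 kept). At an adjusted p under 0.01 the shared sex differences fell from 179 to 105, those of L3 and P6 from 59 to 36 and those of P6 and P20 from 133 to 81, a stricter threshold by construction. Without 1 array the counts ran from 85 to 140 at L3, 388 to 719 at P6, 229 to 263 at P20, 3597 to 4785 and 3287 to 4757 from L3 to P6 in females and males, 2624 to 3199 and 2534 to 2944 from P6 to P20, and 157 to 254 in the interaction. Without both L3 replicate 1 arrays they were 131 at L3, 5083 and 4983 from L3 to P6, and 207 in the interaction. Lists were not refitted without single arrays, apart from innate immunity at P6 and in its change from L3 to P6. Of 319 calls of named genes, 317 kept direction and call with median centring, 315 with the replicate block and 297 whichever single array was left out. With centring the L3 calls of E(spl)m4-BFM (adjusted p = 0.0609) and htl (0.0814) were lost. With the block the P6 call of dpp was gained (adjusted p = 0.0271), while those of Jhbp2 (0.072) and egr (0.0569) at P6 and of E(spl)m4-BFM (0.065) and htl (0.0519) at L3 were lost. Of 59 values from other probe sets of genes past the threshold, 31 kept the call, 24 kept the direction only and 4 turned it, namely dsx at L3, P6 and P20 (5.48, 4.67 and 4.82) and Pxn at P6 (0.10). For Sxl, not past the threshold, 1 of 2 other probe sets gave 1.86, 1.46 and 1.67. The deposited values hold no background signal, so dim genes cannot be told from absent ones.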

Other observations

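Single genes of the innate immunity list rose from P6 to P20 while the list did not pass in either sex. In this list of 11 genes, Tsf1, which encodes an iron-binding transferrin, rose by 3.74 in females and 5.11 in males, CecB by 2.39 and 1.64, and Def by 2.83 and 2.498. Other probe sets of Tsf1 gave 1.52 (adjusted p = 1.54e-07) and 0.22 (adjusted p = 0.13) in females and 2.33 (adjusted p = 1.51e-10) and 0.35 (adjusted p = 0.0149) in males, and the call of Def in males was lost without P6 male replicate 3 (adjusted p = 0.0501). The members past the threshold were 3 higher and 1 lower in females (4 and 1 adjusted over the list alone, adjusted p = 0.626) and 4 higher and 0 lower in males (4 and 0 adjusted over the list alone, adjusted p = 0.132). In P6 female replicate 2 the list's mean lay 2.28 above the group mean, while that of larval fat body markers lay at -0.04.

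Among apoptosis genes, 12 in number, the inducer gene grim rose from P6 to P20 by 1.96 in females and 1.20 in males, and the caspase gene Dcp-1 by 0.64 and 0.46, while the inhibitor gene Diap2 fell by 0.51 and 0.45. The call of Dcp-1 in males was lost without P6 male replicate 3 (adjusted p = 0.0535) or P20 male replicate 4 (0.0502). Past the threshold were 3 higher and 1 lower in females (5 and 1 adjusted over the list alone, adjusted p = 0.298) and 4 higher and 2 lower in males (4 and 3 adjusted over the list alone, adjusted p = 0.72). Dfd, the member of the 4 measured Hox genes that passed, rose by 1.53 in females and 2.40 in males (1 and 0 adjusted over the list alone in each), and the list was too small for its test. Of 8 heat shock genes, Hsp68 rose by 1.64 in both sexes and Hsp27 by 0.76 and 0.73 (2 and 0 adjusted over the list alone in each, adjusted p = 0.381 and 0.136). From L3 to P6 the hindgut transcription factor gene byn fell by 3.43 in females and 3.26 in males, and the muscle genes Prm and Tm2 fell by 3.64 and 4.09 in females and by 3.49 and 3.68 in males; of 19 gut genes 2 were higher and 4 lower in each sex (2 and 4 adjusted over the list alone in each), and of 18 muscle genes 4 were higher and 6 lower in females and 2 and 6 in males (4 and 6, and 2 and 6, adjusted over the list alone), with adjusted p = 0.907 for each list in females and 0.355 in males.

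The annotation names no gene for 4720 probe sets. Of these, 10, 20 and 25 were higher in females at L3, P6 and P20, and 17, 32 and 21 were lower. 1 probe set, among those with the largest female-higher difference at each stage, was higher in females at every stage, by 2.56, 3.79 and 3.82. Whether others were too was not counted.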
